A study of Mus musculus with 31 samples.

How the data were processed

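12 RNA-seq libraries of sorted mouse astrocytes were analysed, 3 in each of 4 groups. Per the labels, C57Bl/6 mice received IL-1β at 100 ng/mL and TNF-α at 50 ng/mL, or PBS, into the lateral ventricles of the brain. Mice labelled 2X were injected again on day 7 and mice labelled 1X were injected on day 7 only, and astrocytes were sorted 18 to 24 hours later. The short description label names TNF-α stimulation only, while the treatment protocol names both cytokines. The markers used in the sort are not given in the sources used here. The 19 ATAC-seq samples of the series were not analysed here. 10 of those have no group, because their title and their treatment label contradict each other.

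Per the file headers, each deposited file lists 142604 transcripts with their length, effective length, estimated count and TPM (transcripts scaled to a fixed sum per library). Per the labels' protocols, libraries were made with the SMART-Seq2 method and reads were assigned to the mouse GRCm38 transcriptome with kallisto 0.46.1, which divides reads that match several transcripts among them by a model. Per the labels' protocols, the submitters tested expression with DESeq2 and shrank fold changes with apeglm; their test results were not used here. The deposited estimated counts were not normalised between libraries, and the deposited TPM values were scaled to the same sum in each library. The deposited effective lengths, in bases, are other values and entered one alternative. Estimated counts were summed per gene over 55401 genes and rounded to whole numbers. Gene positions are those of GENCODE M21 on GRCm38 and are given only where the versioned gene identifier is the same, which held for 98.1% of the genes. Use of strand in the counting is not given in the sources used here, so overlapping and antisense genes cannot be told from each other, and genes with near-identical copies are uncertain.

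Library totals ran from 1878418 to 5521679 estimated counts. A floor of 3 counts lies between 0.543 and 1.60 CPM (counts scaled to a common library total) in these libraries. PCR copies were not separated from molecules, so depth and floors cover counting error only. The labels do not state whether each library is 1 animal, so p-values measure the spread between libraries, which may be technical.

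Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, after filterByExpr on the 4 groups and TMM scaling, with 1 coefficient per group and all 12 libraries in one fit. This kept 14490 genes. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Standard errors were taken as the log2 fold change divided by the root of F. The 6 comparisons were 1X cytokine against 1X PBS, 2X cytokine against 2X PBS, 2X cytokine against 1X cytokine, 2X PBS against 1X PBS, the difference between both cytokine responses, and their average. Expression is given as CPM on TMM-scaled library sizes, as mean ± SD of 3 libraries.

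The design, the gene lists, a panel of 30 genes, the rule for naming genes and the alternatives were fixed before the data were examined. Named genes come from 4 parts of the rule, applied per comparison. The first is the 8 largest log2 fold changes in each direction among protein-coding genes past the threshold with a mean CPM of at least 5 and no overlap between the groups, leaving out clone names and, for the difference and the average, the overlap condition. The others are up to 4 members of each function list with the smallest adjusted p, the panel, and, for each list of another cell type, up to 2 members with the highest mean CPM and up to 2 with the smallest adjusted p. Csf2 and Nos2 of the panel did not pass the filter. The text names some of the genes that the rule allows and leaves out the others. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry, over 32 lists. The B cell list had 1 measured gene and was not tested. The level of a list in a library is the geometric mean of CPM + 0.5 over its measured members.

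Alternatives were DESeq2 1.42.0, RLE scaling, no filter beyond 1 count, a filter at a mean CPM of 10, an effective length offset, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 1, voom with sample quality weights, protein-coding genes only, the replicate number as a block, the libraries of a comparison alone, and leaving out each library in turn. Leaving out 1X PBS replicate 1 and 1X cytokine replicate 1 together was added after the data were seen, because each stood apart from the other libraries of its label.

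The procedure was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For 1X cytokine against 1X PBS, edgeR recovered 27 of the 2-fold and 76 of the 4-fold genes among 14232 tested, with 4 false calls. For 2X cytokine against 2X PBS it recovered 38 and 79 among 14246, with 10 false calls. For the difference between responses it recovered 9 and 56 among 14246, with 2 false calls. DESeq2 recovered 41 and 82, 47 and 87, and 25 and 72 in the same order, with 22 false among 145 calls, 33 among 167 and 21 among 118. The simulation drew each gene independently and holds no variation shared between genes. It gave all groups the spread of the fit of 12 libraries, where the coefficient of variation between libraries was 0.237. That coefficient was 0.309 in the 1X libraries alone and 0.114 in the 2X libraries alone. The recovered shares therefore do not measure what the tests can find at the spread of the 1X or of the 2X libraries. No pair of replicates agreed within sampling noise: the chi-square per gene ran from 3.42 to 53.59 over the 12 pairs, so no pair was counted as a repeat deposit of 1 library. This check does not show that the libraries come from separate animals.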

Results

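Gene expression was measured by RNA-seq in 12 libraries of sorted mouse astrocytes, the glial cells that support neurons and become reactive in inflammation. The libraries carry 4 labels with 3 replicates each: 1X PBS, 1X cytokine, 2X PBS and 2X cytokine. Total estimated counts ranged from 1878418 in 1X cytokine replicate 3 to 5521679 in 2X PBS replicate 2. Mitochondrially encoded genes took between 4.29% and 5.83% of the counts. All groups are named below by the labels of their libraries.

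The libraries did not divide by label alone. The first principal component held 46% of the variance. Within the 1X groups, replicates 2 and 3 of 1X PBS scored 67.5 and 67.0 and replicate 1 scored -41.2, while replicate 1 of 1X cytokine scored 39.8 and replicates 2 and 3 scored -29.3 and -38.8. The 3 libraries labelled 2X PBS scored from 11 to 17.8 and those labelled 2X cytokine from -40.7 to -30.0. Lcn2, which encodes an iron-binding acute-phase protein of reactive astrocytes, had a CPM of 5.33, 1076 and 776 in the libraries labelled 1X PBS and of 797, 11.5 and 3.85 in those labelled 1X cytokine. Gfap, the intermediate filament gene of astrocytes, had a CPM of 189, 702 and 585 in 1X PBS and of 725, 234 and 153 in 1X cytokine. Xist was counted in every library, between 709 and 1442 CPM, here on unscaled library totals. On the same totals the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty lay between 0 and 3.39 CPM.

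**Figure D1:**
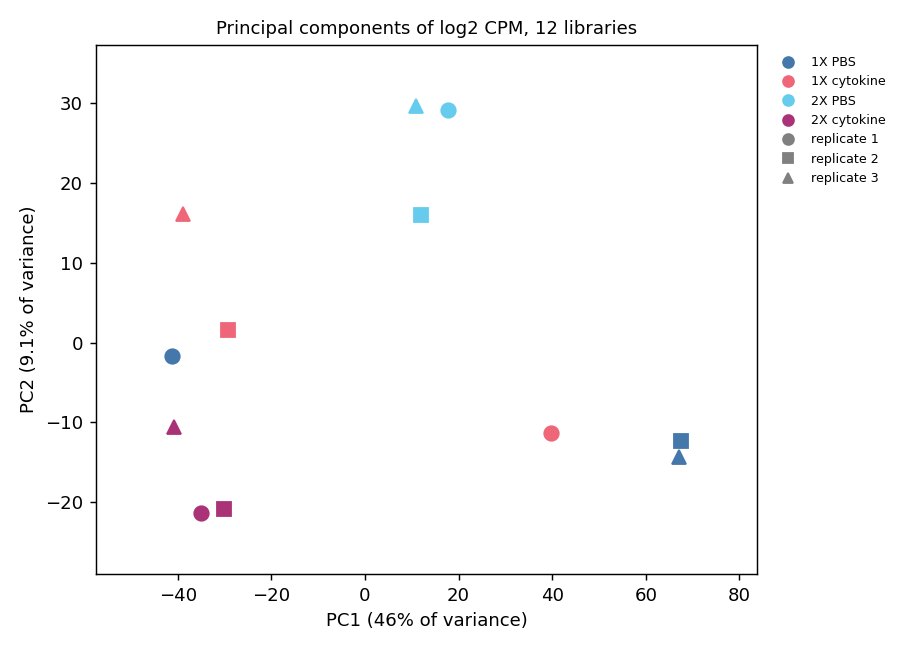
Scores of the 12 libraries on the first and second principal component of log2 CPM (x and y axis, with the share of variance), coloured by label, with the marker showing the replicate number. Replicate 1 of 1X PBS lies at -41.2 and replicate 1 of 1X cytokine at 39.8 on the first component, each away from the other libraries of its label.

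The comparison of 1X cytokine with 1X PBS asks what a single cytokine injection changes. Slc7a10, an amino acid transporter of astrocytes, had a CPM of 529 ± 344 in 1X cytokine and 277 ± 135 in 1X PBS (SD, n = 3), and Fgfr3, a growth factor receptor, had 1098 ± 637 and 482 ± 335. C3, the central complement component, had 207 ± 330 and 553 ± 490, and Cd14, a receptor for bacterial lipopolysaccharide, had 62.8 ± 84.4 and 300.3 ± 252. The larger SD exceeded the difference between the groups for each of these 4 genes, and none passed the threshold. By edgeR 0 genes were called among 14490, 783 had an unadjusted p under 0.05, and DESeq2 called 2, limma-trend 6 and 5 at its pseudocounts, voom with quality weights 1778 and the fit without a low count filter 251. Without 1X PBS replicate 1 edgeR called 1141 genes, without 1X cytokine replicate 1 it called 2, without 2X cytokine replicate 1 it called 3, and without both replicate 1 libraries of the 1X groups 3489.

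Of the 26 homeostatic astrocyte genes 25 had a higher mean in 1X cytokine, with a mean log2 fold change of 0.41, and of the 20 NF-kB targets and regulators 18 had a lower one, with a mean of -0.76. Camera gave adjusted p-values of 4.1e-07 and 8.79e-06 for these lists at the preset correlation, and adjusted p = 0.619 for both with an estimated correlation. The homeostatic mean was 1.21, 0.16 and 0.15 without 1X PBS replicate 1, 2 or 3 and 0.69 and 0.21 without 1X cytokine replicate 1 or 3. No member passed the edgeR threshold over all genes; adjusted over the list alone, 0 homeostatic and 3 NF-kB genes did. In all, 16 of 32 lists were called at the preset correlation and 0 with an estimated correlation or by fry. Of the lists of other cell types, the monocyte and macrophage list had a mean log2 fold change of -2.26 with 12 of 12 members lower, and the erythrocyte list -2.17 with 7 of 7 lower, both at adjusted p = 0.619 with an estimated correlation. Adjusted over the list alone 1 monocyte and 5 erythrocyte markers passed, against 0 over all genes. The monocyte mean was -4.26 without 1X cytokine replicate 1 and the erythrocyte mean -1.13 without 1X PBS replicate 3. A lower mean was also seen for 13 of 15 endothelial, 17 of 20 microglia and 12 of 12 ependymal markers, at mean log2 fold changes of -0.88, -0.86 and -0.27. Camera gave these lists adjusted p-values of 0.000225, 9.07e-05 and 0.012 at the preset and adjusted p = 0.619, 0.619 and 0.747 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. The endothelial mean was -0.48 without 1X PBS replicate 3 and -1.56 and -0.55 without 1X cytokine replicate 1 or 2. The ependymal mean was -0.44 and -0.48 without 1X PBS or 1X cytokine replicate 1, and its call was lost at -0.03 and -0.07 without 1X PBS or 1X cytokine replicate 2. The microglia call was lost without 1X cytokine replicate 1, at -0.90.

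The comparison of 2X cytokine with 2X PBS asks the same after repeated injection. Timp1, an inhibitor of matrix metalloproteinases (X, 20870166 to 20874735), fell from 177 ± 17.4 CPM in 2X PBS to 11.5 ± 5.75 in 2X cytokine (SD, n = 3), a log2 fold change of -3.93 with a standard error of 0.40 and an edgeR adjusted p of 0.00542. Inmt, a methyltransferase gene (6, 55170626 to 55175043), fell from 31.2 ± 7.65 to 7.10 ± 1.85 CPM, Tmem176a (6, 48840919 to 48847071) from 241 ± 4.79 to 81.4 ± 17.1, Tspan4, a tetraspanin, from 133 ± 17.3 to 49.4 ± 4.13, and Psmb10, a subunit of the immunoproteasome (8, 105935735 to 105938444), from 41.9 ± 3.94 to 18.5 ± 2.47. Their edgeR adjusted p-values lay between 0.00542 and 0.0278, and no library of one group overlapped the other. These 5 genes, all lower in 2X cytokine, were the calls of edgeR among 14490, and 1402 genes had an unadjusted p under 0.05.

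The fit of these 6 libraries alone called 1065 genes, 731 lower and 334 higher in 2X cytokine, with a biological coefficient of variation of 0.114 against 0.237 in the fit of 12. Genes of the reactive state were lower in 2X cytokine in that fit. Gfap fell from 1093 ± 49.3 to 127 ± 19.8 CPM (log2 fold change -3.09, standard error 0.12), Serpina3n, a serine protease inhibitor, from 781 ± 170 to 28.7 ± 0.85, C3 from 462 ± 151 to 19.9 ± 2.42 and Lcn2 from 453 ± 106 to 6.15 ± 7.68. The adjusted p-values of these 4 genes lay at or below 2.88e-06 in the edgeR fit of 6 libraries and between 0.105 and 0.415 in the fit of 12. Of 13 pan-reactive astrocyte genes 9 passed the threshold in the fit of 6 libraries, all lower, as did 11 of 14 complement and acute-phase genes, 12 of 20 cytokine and chemokine genes and 12 of 20 genes of MHC class I presentation. Over all 14490 genes 25.3% had no overlap between the libraries of both groups, where chance gives 10% on average over splits. That share was 6.18% for 1X cytokine against 1X PBS, 12.5% for 2X against 1X cytokine and 11.4% for 2X PBS against 1X PBS. Genes vary together, so the share of a single comparison can lie away from 10% without an effect. In the fit of 12 the numbers for the 4 lists were 1, 0, 0 and 1 over all genes, and 9, 10, 8 and 11 adjusted over the list alone. Camera called these lists at the preset correlation, with adjusted p-values of 1.48e-09, 3.54e-08, 5.72e-08 and 2.5e-11, and lost them with an estimated correlation, at adjusted p = 0.121 for each.

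Among single genes of these lists, the chemokine gene Ccl2 had 32.2 ± 4.74 CPM in 2X PBS and 3.78 ± 0.49 in 2X cytokine, and the complement gene C4b, which shares sequence with a close paralog, had 428 ± 27.4 and 71.9 ± 2.86. The class I gene B2m had 310.3 ± 29.3 and 148 ± 24.1. Tnfrsf1a, the TNF receptor 1 gene, had 154 ± 19.96 and 67.2 ± 8.66, and the log2 fold change of -1.20 had an edgeR adjusted p of 0.0542 in the fit of 12 libraries. Irf1, an interferon regulatory factor, had 101 ± 13 and 186 ± 34.1, higher in 2X cytokine in the fit of 6 libraries with an edgeR adjusted p of 0.00175. Of the 26 homeostatic genes 20 had a higher mean in 2X cytokine, and in the fit of 6 libraries 7 passed the threshold, all higher, against 0 in the fit of 12 over all genes and 0 adjusted over the list alone. Camera gave this list an adjusted p of 0.125 at the preset and adjusted p = 0.856 with an estimated correlation. Sparcl1, a secreted matrix protein of astrocytes, had 4365 ± 534 CPM in 2X PBS and 6582 ± 565 in 2X cytokine and Apoe, the apolipoprotein E gene, 7564 ± 436 and 9670 ± 358, with edgeR adjusted p-values of 0.00404 and 0.0187 in the fit of 6 libraries. Aqp4, the water channel of astrocyte endfeet, had 688 ± 26.7 and 667 ± 57.3 CPM, and Slc1a2, a glutamate transporter, had 1868 ± 131 and 1722 ± 59.2.

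Lists of other cell types also differed at the preset correlation. In the fit of 6 libraries 8 of 13 oligodendrocyte markers passed the threshold, all higher in 2X cytokine. Mbp, a myelin protein gene, had 455 ± 98.4 CPM in 2X PBS and 1045 ± 338 in 2X cytokine. In that fit 6 of 10 neutrophil, 6 of 12 monocyte and macrophage and 10 of 20 microglia markers passed the threshold, all lower. List sizes are those of the fit of 12. There 12 of 13 oligodendrocyte markers had a higher mean, and 7 of 10 neutrophil, 12 of 12 monocyte and 17 of 20 microglia markers a lower one. In the fit of 12 no member of these 4 lists passed over all genes, and 8 oligodendrocyte, 0 neutrophil, 7 monocyte and 0 microglia markers passed adjusted over the list alone. Camera called the oligodendrocyte list at adjusted p = 3.25e-09 with the preset and adjusted p = 0.19 with an estimated correlation, the monocyte list at 0.000489 and adjusted p = 0.121, and the microglia list at 2.31e-05 and adjusted p = 0.403. It did not call the neutrophil list at the preset, at adjusted p = 0.145. All 7 erythrocyte markers had a higher mean in 2X cytokine, at a mean log2 fold change of 1.79, as had 11 of 12 ependymal markers, at 0.25, while 10 of 10 choroid plexus markers had a lower one, at -0.54, and 9 of 15 mural cell and fibroblast markers, at -0.44. Camera gave these 4 lists adjusted p-values of 0.000487, 0.00554, 0.00277 and 0.00078 at the preset, and adjusted p = 0.403, 0.592, 0.502 and 0.472 with an estimated correlation. In the fit of 12 no member passed over all genes, and 2 mural cell and 0 other members did so adjusted over the list alone. In the fit of 6 libraries 6 mural cell members passed, all lower, and 2 ependymal members, both higher. There 0 erythrocyte and 0 choroid plexus members passed. Without 2X cytokine replicate 1 the erythrocyte and choroid plexus means were 0.77 and -0.26 and both calls were lost, and the ependymal mean was 0.38. Without 2X cytokine replicate 3 the choroid plexus and mural means were -0.95 and -0.23, and the ependymal call was lost at 0.19, as it was at 0.15 without 2X PBS replicate 3. In all, 17 of 32 lists were called at the preset correlation, 0 with an estimated correlation and 0 by fry in 1 direction. Fry's mixed test, which takes changes in either direction, called 2, the pan-reactive and MHC class I lists, at adjusted p-values of 0.00785 and 0.0198. The count of 5 genes moved with single libraries. It was 125 without 1X PBS replicate 1, 19 without 1X cytokine replicate 1, 11 without 1X cytokine replicate 3, 3 without 1X cytokine replicate 2, 2 without 1X PBS replicate 2 or any 2X PBS library, 0 without 2X cytokine replicate 2 or 3, and 1042 without both replicate 1 libraries of the 1X groups. DESeq2 called 114 genes, voom with quality weights 454 and the fit without a low count filter 460.

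**Figure D2:**
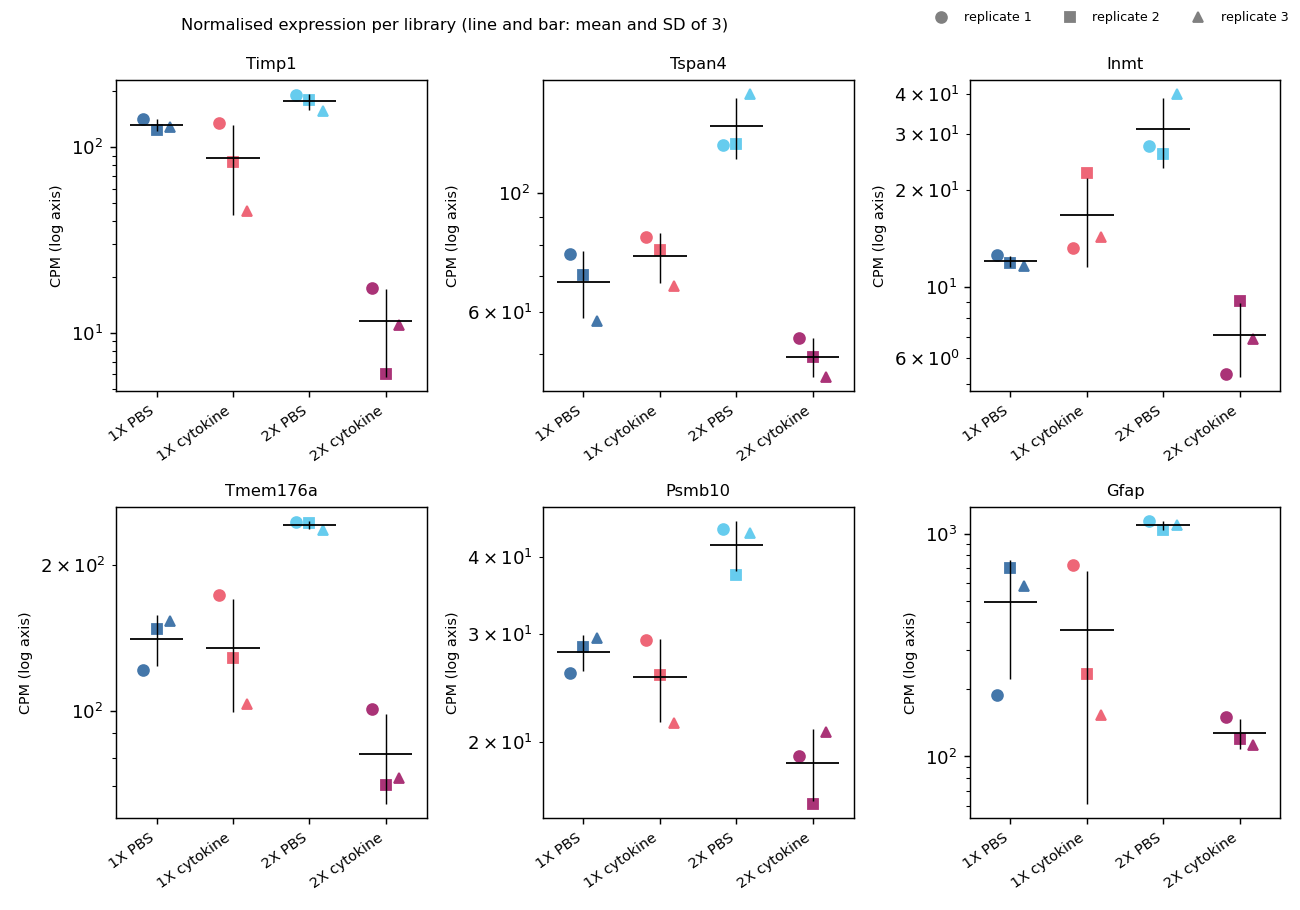
CPM (log axis) of the 5 genes called in 2X cytokine against 2X PBS and of Gfap, per library and label; the marker shows the replicate number, and the line and bar give the mean and SD of 3. Timp1 lies at 11.5 CPM on average in 2X cytokine and at 177 in 2X PBS, and Gfap at 127 and 1093.

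The comparison of 2X cytokine with 1X cytokine asks whether a second cytokine exposure gives another state than a first. Timp1 was lower in 2X cytokine, at 11.5 ± 5.75 CPM against 87.9 ± 44.7 in 1X cytokine (SD, n = 3; log2 fold change -2.94, standard error 0.39, edgeR adjusted p 0.0422). The other 3 calls, Gm37375, Gm37385 and Gm43590, fall outside the naming rule and were named after their values were seen. They have one value in every library because the counts are divided among copies of one sequence, so they stand for 1 call at most. Their CPM was 5.59 on average in 2X cytokine and 0.08 in 1X cytokine. In all 1016 genes had an unadjusted p under 0.05, and the fit of these 6 libraries alone called 0. Camera called 13 of 32 lists at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.786, and fry called 0. Of the 13 pan-reactive genes 12 had a lower mean in 2X cytokine, with a mean log2 fold change of -1.55; 1 passed over all genes and 6 adjusted over the list alone. Camera gave this list an adjusted p = 0.0006 at the preset correlation and adjusted p = 0.786 with an estimated correlation. The list's level was 186, 69.5 and 31.5 in the libraries labelled 1X cytokine and 42.8, 35.7 and 30.9 in those labelled 2X cytokine. Without 1X cytokine replicate 1 camera called 6 lists in place of 13, and the pan-reactive list, at a mean of -0.45, was no longer called. Mitochondrially encoded genes were lower in 12 of 13, at -0.23, and nuclear-encoded oxidative phosphorylation genes in 21 of 26, at -0.13. Camera gave these 2 lists adjusted p-values of 0.000499 and 0.00562 at the preset and adjusted p = 0.786 for both with an estimated correlation. Choroid plexus markers had a mean log2 fold change of -1.03 with 10 of 10 lower, at adjusted p = 3.38e-07 with the preset and adjusted p = 0.786 with an estimated correlation. All 12 ependymal and all 7 erythrocyte markers had a higher mean, at 0.30 and 0.96, and 14 of 15 mural cell and fibroblast markers a lower one, at -0.41. Camera gave adjusted p-values of 0.00173, 0.0435 and 0.00961 for these lists at the preset and adjusted p = 0.786 for each with an estimated correlation. No member of these 4 lists passed over all genes or adjusted over the list alone. Without 1X cytokine replicate 1 the ependymal, erythrocyte and mural means were 0.55, 2.03 and 0.06. The ependymal call was lost at 0.15 without 1X cytokine replicate 2. The erythrocyte mean was -0.06 without 2X cytokine replicate 1, and its call was lost at 0.53 and 0.77 without 1X cytokine replicate 2 or 3, at 1.18 without 2X cytokine replicate 2 and at 0.96 and 0.98 without 1X PBS replicate 1 or 2. The mural mean was -0.62 without 1X cytokine replicate 3, and its call was lost at -0.21 without 2X cytokine replicate 3. Leaving out 1 library gave 0 calls for 10 of the 12 libraries, 1 call without 1X cytokine replicate 3 and 3 without 2X cytokine replicate 1, and leaving out both replicate 1 libraries of the 1X groups gave 3. DESeq2 called 8, the fit without a low count filter 193, and protein-coding genes alone gave 0.

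The comparison of 2X PBS with 1X PBS asks what the schedule changes without cytokine. It cannot tell the schedule from a batch that goes with it. No gene passed the threshold by edgeR, 914 had an unadjusted p under 0.05, DESeq2 called 17, limma-trend 1 and 0 at its pseudocounts, voom with quality weights 2699 and the fit without a low count filter 97. Gfap had 1093 ± 49.3 CPM in 2X PBS and 492 ± 269 in 1X PBS (SD, n = 3). All 13 oligodendrocyte markers had a lower mean in 2X PBS, with a mean log2 fold change of -0.77, and 11 passed adjusted over the list alone, against 0 over all genes. All 14 genes of synaptic neurotransmitter handling had a higher mean, at 0.59, but the level of this list was 282, 100.4 and 101 in the libraries labelled 1X PBS and 251, 243 and 249 in those labelled 2X PBS, so that 1X PBS replicate 1 lay above every 2X PBS library. Of its genes 0 passed over all genes and 0 adjusted over the list alone, and its mean was 1.33 without 1X PBS replicate 1, 0.36 without replicate 2 and 0.35 without replicate 3. The erythrocyte list had a mean of -3.00 with 7 of 7 lower and the endothelial list -1.03 with 14 of 15 lower; 5 and 1 of their genes passed adjusted over the list alone and 0 over all genes, and camera gave adjusted p-values of 2.38e-06 and 2.68e-05 at the preset and adjusted p = 0.914 for both with an estimated correlation. Without 1X PBS replicate 3 the means were -1.95 and -0.62. Immediate-early and dissociation-response genes had a mean of -0.43 with 18 of 20 lower, and -0.22 without 1X PBS replicate 3. Camera gave this list an adjusted p of 0.000113 at the preset and adjusted p = 0.914 with an estimated correlation. Of its genes 0 passed over all genes and 0 adjusted over the list alone. Camera called 8 of 32 lists at the preset correlation, among them the oligodendrocyte and synaptic lists with adjusted p-values of 1.16e-11 and 8.34e-07, and gave adjusted p = 0.914 for both with an estimated correlation, where 0 lists were called, as by fry. Without 1X PBS replicate 1 edgeR called 1116 genes, and without both replicate 1 libraries of the 1X groups 2759.

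Whether the cytokine response differed between schedules was tested as the difference of the log2 fold changes. No gene passed by edgeR, 754 had an unadjusted p under 0.05, DESeq2 called 13, limma-trend 1 and 2 at its pseudocounts, voom with quality weights 199 and the fit without a low count filter 70. For Tspan4 the difference was -1.60 with an adjusted p of 0.109, for Inmt -2.61 with 0.133 and for Timp1 -3.36 with 0.155 (edgeR). Without 1X PBS replicate 1 edgeR called 17 genes, and without both replicate 1 libraries of the 1X groups 1386. Camera called 17 lists for this difference at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.782.

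Averaged over both schedules, Timp1 was the only call of edgeR among 14490 genes, with a log2 fold change of -2.25, a standard error of 0.26 and an adjusted p of 0.0301, and 1481 genes had an unadjusted p under 0.05. Timp1 was called in the 2X comparison, where its change was larger than this average. It was not called in the 1X comparison, which called 0 genes. DESeq2 called 195, limma-trend 8 and 4 at its pseudocounts, voom with quality weights 2478, the effective length offset 2 and the fit without a low count filter 637. That count was 1624 without 1X PBS replicate 1, 176 without 1X cytokine replicate 1 and 3444 without both, and it was 0 without any 1 of 8 other libraries: 1X PBS replicates 2 and 3, 1X cytokine replicate 2, the 3 libraries labelled 2X PBS and 2X cytokine replicates 2 and 3. All 20 measured genes of MHC class I presentation had a lower mean in the cytokine libraries, at a mean log2 fold change of -0.65, with 0 past the threshold over all genes and 11 adjusted over the list alone. The monocyte and macrophage list had -2.50 with 12 of 12 lower. Camera gave adjusted p-values of 1.05e-12 and 6.93e-06 for these lists at the preset correlation and adjusted p = 0.375 for both with an estimated correlation, and it called 19 of 32 lists at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.375, and fry called 0. A lower mean in the cytokine libraries was also seen for 14 of 15 endothelial, 17 of 20 microglia, 11 of 15 mural and 8 of 10 neutrophil markers, at -0.43, -0.92, -0.15 and -1.59, and a higher one for 11 of 13 oligodendrocyte markers, at 0.26. Camera gave these 5 lists adjusted p-values of 0.00758, 1.58e-07, 0.046, 0.0341 and 0.000698 at the preset and adjusted p = 0.649, 0.375, 0.679, 0.649 and 0.479 with an estimated correlation. No member passed over all genes; of the monocyte list 9, of the microglia list 9, of the neutrophil list 4 and of the other 3 lists 0 did so adjusted over the list alone. The endothelial call was lost at -0.23 and -0.26 without 1X PBS replicate 3 or 1X cytokine replicate 2, the neutrophil call at -1.25 and -1.23 without 1X cytokine replicate 2 or 2X cytokine replicate 3, and the oligodendrocyte call at 0.23 without 1X cytokine replicate 1. The mural call was lost at -0.05, -0.08, -0.02, -0.11 and -0.03 without 1X PBS replicate 3, 1X cytokine replicate 2 or 3, 2X PBS replicate 3 or 2X cytokine replicate 3. Without 1X cytokine replicate 1 the endothelial, mural and neutrophil means were -0.76, -0.36 and -2.89, without 2X cytokine replicate 1 the neutrophil mean was -2.42, and without 1X cytokine replicate 3 the oligodendrocyte mean was 0.40.

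Across the 14490 genes the log2 fold changes of the 1X and 2X cytokine comparisons, which share no library, had a Spearman correlation of 0.195 and a Pearson correlation of 0.409, and 56.0% had the same sign. Genes are not independent replicates, so these values describe the libraries. The Spearman correlation was 0.101 without 1X PBS replicate 2, 0.073 without 1X PBS replicate 3, 0.119 without 1X cytokine replicate 3 and 0.313 without both replicate 1 libraries of the 1X groups. No overlap of called genes could be formed, because the 1X comparison called 0.

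**Figure D3:**
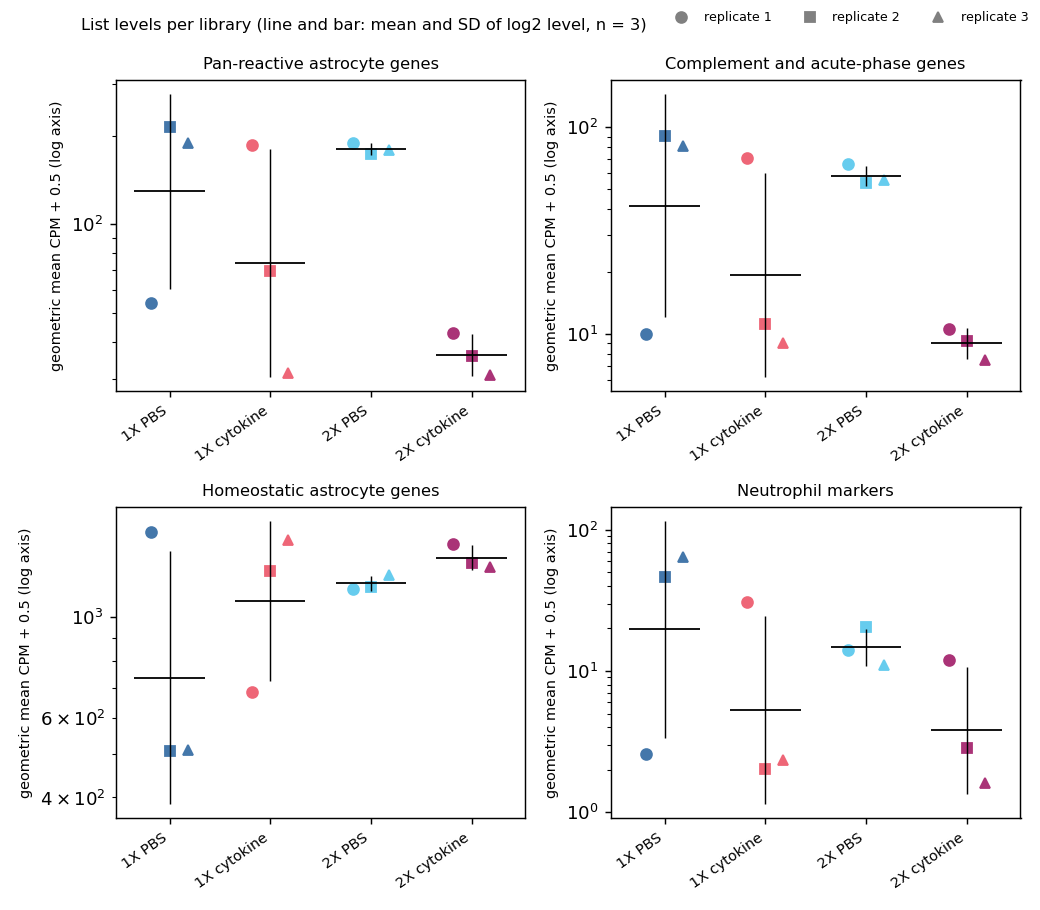
Level of 4 gene lists per library, as the geometric mean of CPM + 0.5 (log axis), by label; the marker shows the replicate number, and the line and bar give the mean and SD of the log2 level over 3 libraries. The pan-reactive list lies at 189, 173 and 178 in 2X PBS, at 42.8, 35.7 and 30.9 in 2X cytokine, at 54.0, 213 and 189 in 1X PBS and at 186, 69.5 and 31.5 in 1X cytokine.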

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

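The tests of a 1X library exchange, of exchanged 2X labels and of white blood cells as a source, the splits of the 1X comparison and the fit without both replicate 1 libraries of the 1X groups were chosen only after the result was seen.

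By camera at the preset correlation, 17 lists differed between the 2X and the 1X cytokine response. With an estimated correlation none of these passed, at adjusted p-values from 0.782 to 0.844. The mean difference (2X minus 1X, log2) was -1.03 for A1-type, -1.72 for pan-reactive, -2.15 for complement and acute-phase, -1.01 for cytokine and chemokine, -0.25 for interferon-stimulated and -0.33 for MHC class I genes. It was -0.22 for homeostatic astrocyte genes, -0.46 for synaptic neurotransmitter handling, -0.24 for extracellular matrix, -0.61 for choroid plexus and -0.58 for mural cell and fibroblast markers. It was 0.35 for NF-kB targets, 0.33 for immediate-early genes, 0.90 for endothelial, 0.52 for ependymal, 3.96 for erythrocyte and 0.75 for oligodendrocyte markers. Without both replicate 1 libraries of the 1X groups the values turned positive for 6 lists, at 0.07, 0.55, 0.73, 0.44 and 0.31 for A1-type, complement, cytokine, interferon-stimulated and MHC class I genes and 0.05 for choroid plexus markers. Leaving out 1 library moved all but the erythrocyte and oligodendrocyte values by over 1.5 times. Without 1X cytokine replicate 1 they were 0.17, 0.37, 0.24 and 0.08 for complement, cytokine, interferon-stimulated and MHC class I genes, -0.19 for A1-type, -0.64 for pan-reactive, -0.72 for synaptic, -0.49 for homeostatic, -0.01 for matrix and 0.67 for NF-kB genes, and -0.29, -0.13 and 1.60 for choroid plexus, mural and endothelial markers. Without 1X PBS replicate 1 they were -0.67 for cytokine, -0.05 for interferon-stimulated, -0.12 for MHC class I, -1.0 for homeostatic, -1.19 for synaptic, 0.61 for NF-kB and 0.56 for immediate-early genes and -0.30 for choroid plexus markers. They were, without 1X PBS replicate 2, 0.05 for homeostatic, -0.21 for synaptic and 0.14 for NF-kB genes and 0.30 for ependymal markers. Without 1X PBS replicate 3 they were 0.04 for homeostatic, -0.22 for synaptic, -0.40 for interferon-stimulated, -0.53 for MHC class I, 0.20 for NF-kB and 0.13 for immediate-early genes and 0.50 for endothelial markers. Without 1X cytokine replicate 2 endothelial and ependymal markers gave 0.58 and 0.34, and without replicate 3 matrix, homeostatic, synaptic, NF-kB and immediate-early genes gave -0.37, -0.01, -0.26, 0.23 and 0.16. Interferon-stimulated genes gave -0.14 without 2X PBS replicate 1, choroid plexus markers -0.34 and -1.05 without 2X cytokine replicate 1 or 3, and matrix genes -0.15 without the latter. Camera called 9 to 16 lists over these settings. Voom with quality weights gave 0.16, 0.25 and 0.13 for cytokine, interferon-stimulated and MHC class I genes. Among 100 splits that regrouped the libraries within each schedule, 30 gave at least 17 lists and the highest other gave 24, so chance is not excluded. For genes, the real count was 0, all 100 splits gave as many and the highest other gave 2272.

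The 1X libraries do not divide by their labels. Among the 10 splits of these 6 libraries, too few for a share under 0.05, the real one called 0 genes, all 10 called as many or more, and the highest other called 4193; that split sets 1X PBS replicates 2 and 3 and 1X cytokine replicate 1 against the rest and points to a structure of the samples. The neutrophil list divides in the same way, at levels of 46.4, 63.9 and 31.0 against 2.59, 2.03 and 2.36 in the rest. The homeostatic astrocyte list does so at 507, 509 and 686 against 1549, 1266 and 1482. The monocyte and macrophage list also does so, at 31.1, 27.4 and 8.79 against 1.95, 1.51 and 2.3. Oligodendrocyte markers do not, at 231, 190 and 214 against 200, 233 and 124. Microglia markers do not either, at 75.8, 81.8 and 28.9 against 23.6, 30.4 and 38.9. Whether the content of other cells divides these libraries was not tested. Counting error from unequal library size is argued against, since the first component's scores correlated at 1 with those after thinning every library to the smallest total. The scores were already scaled for library totals, so thinning tests counting error only and not other traits that go with library size. An exchange of both replicate 1 libraries stays open. So does an exchange of replicates 2 and 3 of both groups, which gives the same split, and the split does not tell which libraries would be affected. The rank correlation across genes with the 2X comparison, which shares no library, was computed for each split. It was 0.347 with both replicate 1 libraries exchanged and 0.292 and 0.273 for the next 2 splits. It was 0.195 for the labels and lowest, at -0.278, with 1X cytokine replicate 3 in place of 1X PBS replicate 3. The lead of 0.055 lies under 0.062, the SD of the labelled split over leaving out 1 library. That SD is not the spread of the lead itself, which was not measured, so this test cannot decide. The order also assumes the 2X labels: were those exchanged, every sign would turn. Each split was scored in 1 direction only, taking as PBS the side that held more libraries labelled PBS. With exchanged 2X labels the opposite direction of the first split would score highest, at 0.347. That direction takes 1X PBS replicate 1 and 1X cytokine replicates 2 and 3 as PBS. Differences between animals stay open too and were not tested. The sequence of Gm37375, picked after its values were seen, was at or below 0.25 CPM in all 3 libraries labelled 1X cytokine. It was at or above 2.86 in the other 9, which follows the labels. A single picked sequence does not decide between the labels and an exchange. Over all 14490 genes 896, or 6.18%, had no overlap between 1X PBS and 1X cytokine, where chance gives 10% on average.

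Pan-reactive genes were lower in the libraries labelled 2X cytokine than in 2X PBS, the opposite of what these cytokines are known to induce. Counting error from unequal library size is argued against: the list's median log2 fold change was -1.96 after thinning to the smallest total and -2.04 before. Other traits that go with library size were not tested by thinning. White blood cells as the one source were not decided by the log2 ratio of the list to the neutrophil and monocyte lists, which differed by 0.67 between 2X PBS and 1X PBS against an SD of 1.3 in 1X PBS, where replicate 1 had 4.6 and the others 2.52 and 2.23. In the 2X libraries this ratio to the neutrophil and monocyte lists was 3.9, 3.52 and 3.93 in 2X PBS and 2.89, 3.79 and 4.36 in 2X cytokine. These values overlap, as white blood cells as the one source would give, but do not decide it. For Gfap, an astrocyte gene, its 1093 CPM in 2X PBS and 127 in 2X cytokine argue against this source, since Lyz2, on average the most abundant marker of these lists in 2X PBS, had 306 and 28.7; for the list it stays open. Exchanged PBS and cytokine labels cannot be told apart from a response that is lower after repeated cytokine: 10 of the 13 genes were lower in every library labelled 2X cytokine, and nothing in the files records the injected solution, so repeated cytokine stays open as the design's own explanation, untested.

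The 10 splits of 6 libraries are too few for a share under 0.05. For 2X cytokine against 2X PBS the real split, 1 of 10, called 5 genes and the highest other 0; in the fit of 6 libraries, also 1 of 10, it called 1065 and the highest other 0. For 2X against 1X cytokine the real split, 1 of 10, called 4 and the highest other 0. For 2X PBS against 1X PBS all 10 called 0. Lists called at the preset correlation numbered 16 in the real 1X split, with 4 of 10 as high and 23 the highest other; 17 in the 2X split, with 1 of 10 and 15; 13 for 2X against 1X cytokine, with 6 of 10 and 23; and 8 for 2X PBS against 1X PBS, with 10 of 10 and 21. For the average over schedules 9 of 100 splits gave at least the 1 gene called, with 2185 the highest other, and 7 gave at least 19 lists, with 23 the highest other, so chance is not excluded for either.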

How the results depend on the processing

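The alternative without both replicate 1 libraries of the 1X groups was chosen only after the data were seen; the libraries were picked on expression, so its counts are not independent evidence.

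Counts are given in the order 1X cytokine against 1X PBS, 2X cytokine against 2X PBS, 2X against 1X cytokine, 2X PBS against 1X PBS, the difference between responses, and the average, where edgeR called 0, 5, 4, 0, 0 and 1. RLE scaling gave these same counts. DESeq2 called 2, 114, 8, 17, 13 and 195 genes. Without a low count filter edgeR called 251, 460, 193, 97, 70 and 637, and the prior degrees of freedom, which set how far gene variances are drawn together, rose from 3.64 to 53.88. Voom with quality weights called 1778, 454, 1, 2699, 199 and 2478, with weights of 0.159 for 1X PBS replicate 1 and 0.307 for 1X cytokine replicate 1 and of 0.905 to 1.644 for the others. Limma-trend called 6, 6, 6, 1, 1 and 8 at a TPM pseudocount of 1 and 5, 7, 9, 0, 2 and 4 at 0.1. The filter at a mean CPM of 10 gave 0, 6, 0, 0, 0 and 1, protein-coding genes alone 0, 5, 0, 0, 0 and 1, and the effective length offset 0, 5, 4, 0, 0 and 2. The libraries of a comparison alone gave 0, 1065, 0 and 0 for the first 4, where the coefficient of variation between libraries was 0.309, 0.114, 0.205 and 0.251 against 0.237 in the fit of 12. Without both replicate 1 libraries of the 1X groups the counts were 3489, 1042, 3, 2759, 1386 and 3444, with a coefficient of 0.123. The cause of these changes was not tested.

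Leaving out 1 library at a time gave 0 to 1141, 0 to 125, 0 to 3, 0 to 1116, 0 to 17 and 0 to 1624 genes. Lists called at the preset correlation ranged from 12 to 21, 15 to 21, 6 to 16, 8 to 16, 9 to 16 and 15 to 21, where all libraries gave 16, 17, 13, 8, 17 and 19. The rank correlation of both cytokine responses ranged from 0.073 to 0.286 and was 0.313 without both replicate 1 libraries, against 0.195. With an estimated correlation, and by fry in 1 direction, 0 lists were called in each of the 6 comparisons; fry's mixed test called 2 for 2X cytokine against 2X PBS and 0 in the others. Voom with quality weights called 16 lists for 2X PBS against 1X PBS and 11 for the difference between responses, and leaving out both replicate 1 libraries gave 19 for 2X PBS against 1X PBS.

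Over all alternatives, 23 values of list results changed the sign of the mean or the direction of camera. For the difference between responses, voom with quality weights gave 0.16 for cytokines and chemokines, 0.25 for interferon-stimulated genes and 0.13 for MHC class I presentation. Without both replicate 1 libraries it was 0.07 for A1-type, 0.05 for choroid plexus, 0.55 for complement, 0.73 for cytokine, 0.44 for interferon-stimulated and 0.31 for MHC class I genes. In that setting mural cell markers in 2X against 1X cytokine gave 0.05 and homeostatic genes there and mitochondrially encoded genes in the average values that round to 0.00, as did limma-trend at both pseudocounts for the latter. Leaving out 1 library gave, for the difference between responses, -2.53 to 0.17 for complement, -1.31 to 0.37 for cytokine, -0.40 to 0.24 for interferon-stimulated, -0.53 to 0.08 for MHC class I and -1.0 to 0.05 for homeostatic genes. For 2X against 1X cytokine it gave 0.00 to 0.47 for homeostatic genes, -0.62 to 0.06 for mural cell and -0.06 to 2.03 for erythrocyte markers. The cause was not tested for these.

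With the replicate number as a block, edgeR called 0, 2, 0, 0, 0 and 1 genes, so the count fell from 5 to 2 and from 4 to 0 for 2X cytokine against 2X PBS and for 2X against 1X cytokine. No positive pairing by replicate number was seen: deviations of same-numbered libraries correlated between -0.623 and 0.163 over 18 pairs, and 2 of these exceeded 0.1. The lowest values were those of 1X PBS with 1X cytokine, at -0.623, -0.299 and -0.389 for replicates 1, 2 and 3. The rule counted only values above 0.1, so it did not register these opposite deviations, and their cause was not tested. Libraries with different numbers were not compared for reference, so this check cannot exclude a shared batch. Depth limits genes near the floor, which lies between 0.543 and 1.60 CPM.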

Other observations

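Across the 12 libraries the level of the list of histone acetylation and acetyl-CoA supply genes lay between 67.1 and 75.2, and that of histone deacetylases and other chromatin regulators between 49.1 and 54.0. The first list had a mean log2 fold change of -0.03 in 2X cytokine against 2X PBS over 19 measured genes, and the other 0.05 over 20, with camera adjusted p-values of 0.806 and 0.144. Ep300, a histone acetyltransferase gene, had 53.8 ± 7.54 CPM in 2X PBS and 49.7 ± 2.12 in 2X cytokine (SD, n = 3), and Acly, which makes acetyl-CoA from citrate, had 239.9 ± 26.5 and 209 ± 16.8. Neither passed the edgeR threshold in the fit of 12 or of 6 libraries.

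The homeostatic astrocyte list had a level of 507 and 509 in 1X PBS replicates 2 and 3 and of 686 in 1X cytokine replicate 1, and between 1158 and 1549 in the other 9 libraries. The erythrocyte list ranged from 34.6 in 2X PBS replicate 3 to 1696 in 1X PBS replicate 3. 2 transcripts, picked after their values were seen, came mainly from single libraries. Prl, the pituitary hormone prolactin, had 230.2 CPM, here on unscaled library totals, in 2X cytokine replicate 1 and at most 20.9 elsewhere, and Krt14, an epidermal keratin, had 105 CPM in 1X cytokine replicate 2 and at most 5.34 elsewhere.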
